A study of Rattus norvegicus with 71 samples.

How the data were processed

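The samples were rat primary cortical cells plated at 150000 cells per well on microelectrode array plates. Per the labels, dosing began 2 h after plating, the test solutions were renewed on days in vitro 5, 7 and 9, and RNA was collected on day 12. Total RNA was taken with the RNeasy Plus kit from 2 to 3 pooled wells per sample, in 2 separate cultures, and polyA-selected libraries were made with the PrepX kit. Sequencing projects GRC321 and GRC327 were read from the sample titles.

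The authors named Partek and STAR as their tools, and neither versions nor roles, the genome build or the strandedness were given in the sources used here. The deposited count table holds expected counts, that is estimated reads per gene without scaling between libraries, for 19771 genes, and 20.6% of its values are not whole (tolerance 1e-06). The deposited normalized table holds CPM, counts scaled to each library's total in the count table, with an offset of 1e-04 added to every value. It differed from values recomputed this way by at most 9.4e-06 in relative terms, among values of 1 CPM or more. The analysis used the expected counts, rounded to whole numbers. CPM levels in the report are group means with SD, or values per library. Unlike the deposited CPM, they were scaled to library totals multiplied by TMM factors, which ran from 0.875 to 1.155.

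Groups were the compound and concentration in the labels. Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, after filterByExpr by group with a minimum count of 10, which kept 15343 genes. One quasi-likelihood model held all 71 libraries, 1 coefficient per group and 1 project term per compound, 31 columns in all, with 40 residual degrees of freedom, so that groups of 1 to 3 libraries shared an estimate of the spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called, and adjusted p values are from this model unless another tool is named. The comparisons were each concentration against the 0 µM libraries of the same compound, a trend over 0 µM and the 3 concentrations with 3 libraries each, and the difference between the effects of related compounds at matched concentrations. The trend was linear over the rank of the concentrations, taken as evenly spaced. Intervals of the differences are at 95%. All tests were 2-sided. The common biological coefficient of variation was 15.6%.

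Totals ran from 7.4 M to 11.8 M in GRC321 and from 5.2 M to 43.1 M in GRC327. In simulated data of this design the method called 40.6% (5-fluorouracil) to 70.3% (cytosine arabinoside) of genes with a log2 change of 1, and 72.3% to 86.4% of those with a change of 2. Between 1.8% and 4.9% of the calls in the simulated data were false. The simulated libraries held no project, culture or run difference and no outlying library, so these shares may not carry over to the real comparisons.

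Gene lists, written before the data were examined, covered cell types, namely markers of oligodendrocyte lineage, astrocytes, microglia, erythroid cells, vascular and fibroblast cells, choroid plexus and ependymal cells, and pan-neuronal, glutamatergic and GABAergic neurons. Further lists covered the cell cycle, p53 targets, nucleotide metabolism, apoptosis and necrosis, activity-regulated genes, presynaptic vesicle genes, ionotropic glutamate receptors, GABA receptors, sodium and calcium channels, potassium channels, and dopamine and monoamine signalling. The rest covered cholesterol biosynthesis, fatty acid synthesis, lysosome, the unfolded protein and integrated stress response, NRF2 targets, xenobiotic response, interferon response, inflammation and reactive glia, and extracellular matrix and growth factors. They were tested with camera (limma 3.58.1, preset correlation 0.01, on voom values), which compares a list with all other genes. Lists at the highest concentrations were adjusted over 162 tests, those at lower concentrations as a separate family, and lists with fewer than 5 tested members were not tested. Marker lists describe levels of RNA in bulk libraries, not numbers of cells. Rrm2, Sv2b and Gpnmb each stand in 2 lists.

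The genes named were set by a rule fixed before the data were examined. For each highest concentration they were the 8 largest rises and the 8 largest falls among called genes with a symbol and an average log2 CPM of at least 0, or every called gene when fewer than 16 passed, or the 6 with the smallest p when none passed, given as values. For each list described they were up to 4 members with the smallest p, and for the differences the 5 largest in each direction. Exceptions are said to be named after their values were seen. Of the 178 genes so named, 21 overlap another gene model (models up to 2000 kb) and may share reads with it.

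The alternatives tried were DESeq2 1.42.0 with its own test or its size factors, limma on the deposited CPM, no filter, a minimum count of 50, no project term, a single project term, GRC327 alone, a fit per compound, all 0 µM libraries pooled, replicate blocks, and leaving out each library in turn. Leave-outs of single libraries kept the gene filter, TMM factors and negative binomial spread of the main fit. They refitted the coefficients and the quasi-likelihood spread. Replicate blocks were the unbroken runs of sample numbers in the titles within a compound. Runs were taken as pairing the samples where the difference between the 2 runs of GRC327 correlated across genes, between every pair of concentrations, above 0.1. This held for haloperidol (0.13 to 0.37), cypermethrin (0.11 to 0.3) and cytosine arabinoside (0.12 to 0.36), and not for domoic acid, deltamethrin and 5-fluorouracil, whose lowest values were −0.03, 0.01 and 0.098. Overlap between compounds was tested with Fisher's exact test against the genes tested. The model was tested on simulated data before use. Among 23 pairs of libraries of the same group within GRC327 no duplicate was found, and other pairs were not checked.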

Results

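RNA was sequenced from rat primary cortical cultures grown on multi-well microelectrode arrays and exposed to haloperidol, domoic acid, deltamethrin, cypermethrin, cytosine arabinoside or 5-fluorouracil until day in vitro 12. The 71 libraries fell into 25 groups, defined by compound and concentration, and each compound had its own 0 µM libraries, 16 in all. There were 22 groups of 3 libraries, 2 groups of 2 libraries (0 µM of cypermethrin and of 5-fluorouracil) and 1 group of 1 library (deltamethrin 0.3 µM). The libraries came from 2 sequencing projects, 24 from GRC321 and 47 from GRC327. GRC321 held 1 library of every group except 5-fluorouracil 0 µM. Total counts ran from 5.2 M to 43.1 M per library, with a median of 10.2 M. Each sample was a pool of 2 to 3 wells, the experiment was run on 2 separate cultures, and the culture behind each library was not given, so the p-values measure the spread between these samples. The question throughout was which genes each compound changed against its own 0 µM libraries, and how the change moved with concentration. Coordinates are those of the deposited table, whose genome build was not given in the sources used here.

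Cytosine arabinoside is a nucleoside analog that blocks DNA synthesis, and its comparison asks how gene expression in the cultures changed under it. At 1 µM most tested markers of the oligodendrocyte lineage and of astrocytes fell, many of them steeply. Pdgfra (chromosome 14, 35527927 to 35581032), the growth factor receptor of oligodendrocyte precursors, fell from 570 ± 40.9 to 4.44 ± 2.55 CPM (SD, n = 3 each), a log2 fold change of −6.95 ± 0.24 (SE; adjusted p = 2.6e-28). Aqp4, the astrocytic water channel, fell from 913 ± 410 to 9.14 ± 4.87 CPM. Top2a, a topoisomerase of dividing cells, fell from 85.3 ± 8.9 to 1.24 ± 0.787 CPM. In the opposite direction, the activity-induced transcription factor Fos (chromosome 6, 109300433 to 109303300) rose from 3.2 ± 0.968 to 128 ± 59.7 CPM. Gad1, an enzyme of GABA synthesis (chromosome 3, 56861396 to 56902158), rose from 172 ± 14.1 to 869 ± 158 CPM. The test called 5520 of 15343 genes, 35.98%, with 2544 higher and 2976 lower, and of these 724 and 1597 changed at least 2-fold. The share of counts in mitochondrial genes was higher at 1 µM than at 0 µM in each run of libraries, at 9.12% against 4.61% in GRC321, and 3.66% against 2.96% and 3.79% against 3.23% in GRC327, and 9.12% was the highest of all 71 libraries.

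Markers of the oligodendrocyte lineage fell together at 1 µM: 17 of the 18 tested were lower and none was higher, with a median log2 fold change of −4.77 (camera adjusted p = 3.8e-18). With genes near 0 counts set at their bound, the median was −4.90. Cspg4, a proteoglycan of the precursors, changed by −6.93 ± 0.33 (adjusted p = 2e-23). The lineage transcription factors Olig2 and Sox10 (chromosome 7, 120393254 to 120403524) changed by −6.12 ± 0.29 and −7.47 ± 0.41. The member that did not pass, the myelin gene Mog, is named after its value was seen, −0.04 ± 0.15 (adjusted p = 0.86). Of 22 astrocyte markers 21 fell, with a median of −3.85 (adjusted p = 3.7e-23). They included the gap junction gene Gja1 at −5.18 ± 0.25 and the glutamate transporter Slc1a3 at −4.04 ± 0.20. The single astrocyte marker that rose, Gjb6, is likewise named after its value was seen, and went from 0.0399 to 1.21 CPM. Of 38 cell cycle genes 33 fell (34 adjusted over the list alone), with a median of −2.47 (adjusted p = 3.8e-18). Among these, Top2a changed by −6.14 ± 0.31, Cenpf by −5.00 ± 0.29, Cdk1 by −4.86 ± 0.33 and Kif11 by −3.91 ± 0.21.

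Activity-regulated genes, the set induced by calcium entry and synaptic activity in neurons, rose with 1 µM cytosine arabinoside in 32 of 33 members, with a median log2 fold change of 2.80 (adjusted p = 1.1e-31). The transcription factors Fosb, Npas4 (chromosome 1, 220261008 to 220265773) and Fos rose by 5.72 ± 0.48, 5.64 ± 0.40 and 5.31 ± 0.46. The neurotrophin gene Bdnf (chromosome 3, 100768637 to 100819211) rose by 4.57 ± 0.32, the secretogranin gene Scg2 by 3.44 ± 0.21 and the phosphatase gene Dusp4 by 2.92 ± 0.16. The neuropeptide gene Crh (5.49 ± 0.50) and Acan, a core proteoglycan of perineuronal nets (4.56 ± 0.25), were among the 8 largest rises. Gprc5a, an orphan receptor gene, and Mcoln3, an endolysosomal channel gene, completed the 8, at 4.40 ± 0.50 and 4.38 ± 0.72. Of 19 GABAergic neuron markers 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 1.32 (adjusted p = 1.3e-10). The GABA enzymes Gad2 and Gad1 rose by 2.44 ± 0.15 and 2.33 ± 0.16, and the interneuron peptides Vip and Sst by 2.75 ± 0.22 and 2.22 ± 0.20. Calb2, named after its value was seen, was the marker that fell (−2.20 ± 0.25). The pan-neuronal markers moved little as a set, with 5 higher and 2 lower of 18, a median of 0.13 and a camera adjusted p of 0.15. Their largest changes by p were in neurofilament genes, Nefl at 1.15 ± 0.12 and Nefh at 2.35 ± 0.39.

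The 8 largest falls with 1 µM cytosine arabinoside included genes with almost no counts left. Pnlip, a lipase gene, Zfp488, an oligodendrocyte transcription factor, and Gask1a had 0 counts in the 3 libraries and were at least 123-fold, 72.1-fold and 58.3-fold lower, against a floor of 3 counts over the group. Nkx2-2, a transcription factor of the oligodendrocyte lineage, had 1 count left and was lower by a ratio of 718 (95% counting interval 129 to 28400). Bmp4, a growth factor gene, and Fmo1 also had 1 count each, with ratios of 469 (84.1 to 18500) and 391 (70.2 to 15500). Plxnb3, a plexin of oligodendrocytes, and Gpr17, a receptor of committed precursors, changed by −9.58 ± 0.59 and −8.16 ± 0.46. Such floors and intervals cover counting error only, since the reads carried no molecular identifiers.

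Further lists moved with 1 µM cytosine arabinoside. Inflammation and reactive glia genes fell in 10 of 17 members and rose in none, with a median of −2.46 (adjusted p = 6.4e-05, and adjusted p = 0.11 with an estimated correlation). The adhesion gene Vcam1 changed by −5.06 ± 0.21 and the hyaluronan receptor Cd44 by −3.37. Oxidative stress (NRF2) targets fell in 12 of 19, with a median of −0.84 (adjusted p = 6.4e-05, and adjusted p = 0.13 with an estimated correlation), among them the heme oxygenase gene Hmox1 at −3.32 ± 0.25. Fatty acid synthesis genes fell in 9 of 16 and rose in 1 (adjusted p = 1.8e-05, and adjusted p = 0.12 with an estimated correlation), including Srebf1, the lipogenic transcription factor, at −4.25 ± 0.21. Extracellular matrix and growth factor genes fell in 12 of 25 and rose in 3 (adjusted p = 0.00022, and adjusted p = 0.059 with an estimated correlation), among them the brevican gene Bcan at −4.67 ± 0.21. Dopamine and monoamine signalling genes rose in 8 of 19 and fell in 3, with a median of 0.61 (adjusted p = 0.0026), led by the opioid peptide gene Penk at 3.15 ± 0.20. With an estimated correlation the oligodendrocyte (adjusted p = 0.0011), astrocyte (0.002), cell cycle (0.036), activity (0.002), GABAergic (0.00086) and dopamine (0.04) calls held.

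The oligodendrocyte markers had fallen at 0.1 µM already, while the astrocyte and activity genes moved further at each higher concentration. Pdgfra changed by −7.25, −7.55 and −6.95 at 0.1, 0.3 and 1 µM. Aqp4 changed by −1.21, −3.0 and −6.65, all past the test. Fos had values of 0.80 (adjusted p = 0.35), 1.64 (0.0068) and 5.31, and Bdnf of 0.88 (0.063), 1.93 (2.3e-06) and 4.57. Gad1 rose at each step, by 1.05, 1.52 and 2.33. At 0.1 µM the oligodendrocyte list had a median of −3.47 with 17 of 18 lower (adjusted p = 2.2e-41), the astrocyte list −0.69 with 12 of 22 lower (1.6e-08, and adjusted p = 0.18 with an estimated correlation), and the activity list 0.23 with 2 of 33 higher (0.017, and adjusted p = 0.88 with an estimated correlation). Cholesterol biosynthesis genes rose in 11 of 25 at 0.1 µM (17 adjusted over the list alone; adjusted p = 7.7e-11, and adjusted p = 0.2 with an estimated correlation), and at 1 µM 3 rose and 4 fell (adjusted p = 0.99). The test called 1401 genes at 0.1 µM (365 higher), 2703 at 0.3 µM (915 higher) and 5547 along the concentration trend.

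The fit within GRC327 alone called 896, 2115 and 4256 genes at 0.1, 0.3 and 1 µM, and gave −6.77 ± 0.32 for Pdgfra, −6.88 for Aqp4, 5.15 for Fos and 2.23 for Gad1 at 1 µM. Without a project term the counts were 505, 1381 and 3113, and without 0.1 µM replicate 2 the count at 0.1 µM was 906. Of the 4246 genes called at 1 µM within GRC327 that were also tested in all libraries, 3816 (89.9%, exact 95% interval over genes 88.9 to 90.8) had the same sign in the single pair of GRC321 libraries, against 60.7% of the genes not called.

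**Figure D1:**
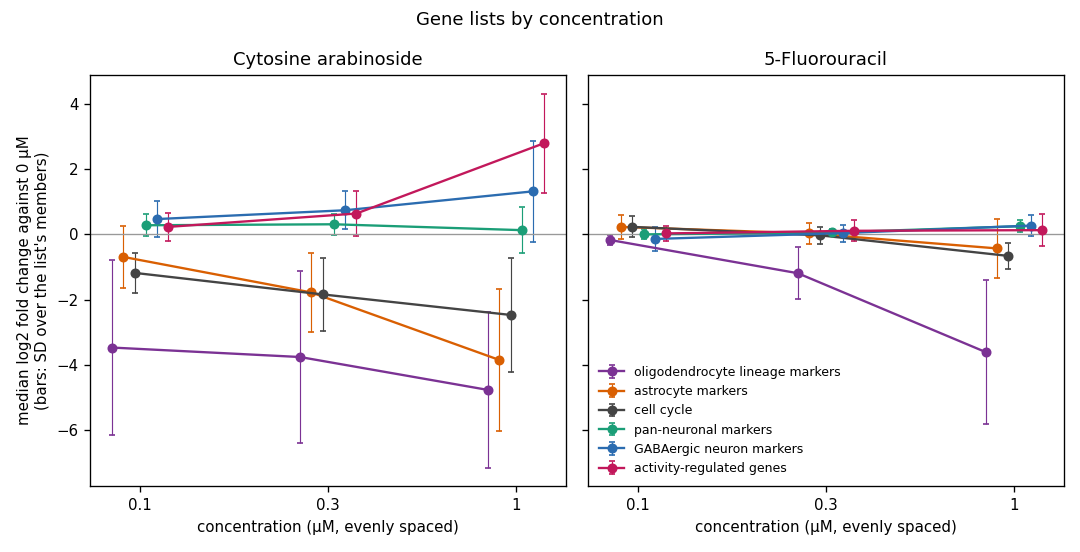
Median log2 fold change against 0 µM of 6 gene lists (vertical axis; bars are the SD over each list's members) at 0.1, 0.3 and 1 µM (horizontal axis) of cytosine arabinoside (left) and 5-fluorouracil (right). The oligodendrocyte lineage median was −3.47 at 0.1 µM cytosine arabinoside and −3.61 at 1 µM 5-fluorouracil, and the activity-regulated median reached 2.80 with 1 µM cytosine arabinoside against 0.13 with 1 µM 5-fluorouracil.

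5-Fluorouracil is a pyrimidine analog that inhibits thymidylate synthase, and it was tested over the same concentrations, so its comparison asks what another antimetabolite changed. At 1 µM oligodendrocyte transcripts fell steeply. Pdgfra went from 514 ± 37.4 CPM (SD, n = 2) to 10.3 ± 5.16 CPM (n = 3), a log2 fold change of −5.73 ± 0.23 (SE; adjusted p = 5e-25), and Sox10 changed by −5.99 ± 0.39 (adjusted p = 2e-16). The 0 µM libraries were all of GRC327, while 1 of the 1 µM libraries was of GRC321. Levels and count ratios of 5-fluorouracil are therefore not matched for project, while the fitted changes hold a project term. Oligodendrocyte lineage markers fell in 17 of 18, with a median of −3.61 (adjusted p = 1.8e-50, and 1.8e-07 with an estimated correlation). Gpr17 and Plxnb3 changed by −6.25 ± 0.42 and −5.68 ± 0.45, and Cspg4 by −3.86 ± 0.27. Pnlip, the phosphodiesterase gene Enpp6 and Bmp4 had 1, 1 and 3 counts left in the 1 µM libraries and were lower by ratios of 311 (95% counting interval 55.8 to 12300), 251 (45 to 9910) and 123 (42 to 595). Inava, an innate immunity gene, changed by −5.78 ± 0.48. The test called 619 genes, 4.03%, with 106 higher and 513 lower, and of these 13 and 289 changed at least 2-fold.

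Astrocyte markers fell with 1 µM 5-fluorouracil in 5 of 22 (8 adjusted over the list alone), with a median of −0.43 (adjusted p = 8.7e-07, and adjusted p = 0.19 with an estimated correlation). Sox9, a glial transcription factor, changed by −0.98 ± 0.19 (adjusted p = 0.00041), and the intermediate filament gene Gfap by −1.75 ± 0.43 (0.0069), which became −1.21 (0.23) without 0 µM replicate 1 and −1.55 (0.095) without 1 µM replicate 3. Id3 changed by −3.58 ± 0.89, with an adjusted p of 0.0089 that became 0.19 without 0 µM replicate 2, 0.11 without 1 µM replicate 2 and 0.056 without 1 µM replicate 3. Gja1 changed by −0.79 ± 0.23 (0.038), a call that ended without 0 µM replicate 1 (0.14) or 2 (0.18) and without 1 µM replicate 2 (0.24) or 3 (0.22). In those fits its change lay between −0.80 and −0.67. Cell cycle genes fell in 4 of 38 (13 adjusted over the list alone), with a median of −0.66 (adjusted p = 9.4e-10, and adjusted p = 0.17 with an estimated correlation). Kif11 (−1.0 ± 0.20), Cenpf (−1.11 ± 0.25), Top2a (−1.04 ± 0.24) and Nusap1 (−1.02 ± 0.24), all of mitosis, made up the 4. Their calls rested on 0 µM replicate 1, without which the adjusted p values were 0.13, 0.076, 0.25 and 0.46, and Nusap1 also lost its call without 1 µM replicate 3 (0.095). Inflammation and reactive glia genes fell in 6 of 17 (8 adjusted over the list alone), with a median of −1.20 (adjusted p = 2.9e-08, and 0.028 with an estimated correlation), among them the sphingosine receptor S1pr3 at −1.69 ± 0.23 and the oncostatin M receptor Osmr at −2.25 ± 0.45.

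Of the neuronal lists with 1 µM 5-fluorouracil, the glutamatergic markers had a median of 0.04 and none of 16 called (camera adjusted p = 0.77). Presynaptic vesicle genes had a median of 0.26 and 2 of 23 higher (adjusted p = 3.3e-07, and adjusted p = 0.05 with an estimated correlation), namely the complexin gene Cplx1 at 0.65 ± 0.12 and the synaptobrevin gene Vamp1 at 0.84 ± 0.16. GABAergic neuron markers had a median of 0.27 and 2 of 19 higher (5 adjusted over the list alone; adjusted p = 0.00022, and 0.042 with an estimated correlation). These were Gad1 at 0.81 ± 0.18 (adjusted p = 0.0031) and the vesicular GABA transporter Slc32a1 at 0.85 ± 0.19 (0.0026), and without 0 µM replicate 2 their adjusted p values were 0.12 and 0.19. With edgeR no pan-neuronal marker of 18 passed, at a median of 0.25 (camera adjusted p = 0.00093, and 0.036 with an estimated correlation). Elavl3, an RNA-binding protein gene, stood at 0.43 ± 0.14 (adjusted p = 0.065) and passed with DESeq2 (0.029), with DESeq2 size factors (0.049), within GRC327 (0.012), against all 0 µM libraries (0.019) and without 1 µM replicate 1 (0.02). Among 33 activity-regulated genes none rose and 1 fell, the pentraxin gene Nptx2 at −0.62 ± 0.16, with a median of 0.13 (adjusted p = 0.17), and Fos stood at 0.13 ± 0.50 (adjusted p = 0.94). Of 28 p53 targets, 1 fell and none rose (Btg2, −0.89 ± 0.26), with a camera adjusted p of 0.8.

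Of the 8 largest rises with 1 µM 5-fluorouracil, Adamts15, a matrix protease gene (1.69 ± 0.26, adjusted p = 8e-06), and Galntl6, a glycosyltransferase gene (1.35 ± 0.27, 0.00062), passed in every leave-out of 1 library. Kank4 (chromosome 5, 117376423 to 117440255) rose by 4.46 ± 0.75 against 2 counts in the pair of 0 µM libraries, a ratio of 23.4 (6.48 to 193). Its 0 µM level of 0.0663 CPM lay below the 0.547 to 1.46 CPM of the other compounds' 0 µM groups, and against all 0 µM libraries together the value was 0.89 (adjusted p = 0.17). Fgd1, whose model overlaps Tsr2, rose by 2.48 ± 0.60 (0.0072), but had 1.96 (0.22) without 0 µM replicate 2 and 0.28 (0.71) against all 0 µM libraries. Gpr83 rose by 1.77 ± 0.38, with an adjusted p of 0.0019 that became 0.058 without 0 µM replicate 1. Epop rose by 1.16 ± 0.32 (0.024), but had 0.69 (0.5) without 0 µM replicate 2 and 0.50 (0.1) against all 0 µM libraries. Its adjusted p was 0.082 without 1 µM replicate 1, 0.088 without 1 µM replicate 3 and 0.11 within GRC327. Fgd5 rose by 1.15 ± 0.26, with 0.0025 that became 0.12 without 0 µM replicate 2 and 0.051 without 1 µM replicate 2. Tox2 rose by 1.06 ± 0.24, with 0.0037 that became 0.052 and 0.058 without 0 µM replicate 1 or 2.

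Few genes were called at the lower 5-fluorouracil concentrations, and those lower at 0.3 µM included myelin genes. At 0.3 µM the test called 7 genes, 1 higher and 6 lower (DESeq2 10, limma 5). Those lower included Cpm, a carboxypeptidase gene (−1.55 ± 0.22, adjusted p = 9.5e-05), Myrf, the myelin regulatory factor (−1.32 ± 0.20, 0.00021), Dusp15 (−1.22 ± 0.21, 0.0026), the galactolipid enzyme Ugt8 (−1.33 ± 0.25, 0.0096) and the myelin glycoprotein gene Mag (−2.06 ± 0.43, 0.035). Cpm passed in every leave-out. Myrf, Dusp15 and Ugt8 lost their calls without 0.3 µM replicate 2 (adjusted p 0.069, 0.15 and 0.58), Dusp15 and Ugt8 without 0 µM replicate 2 (1 and 0.13), Ugt8 without 0 µM replicate 1 (0.19), and Mag in all 5 leave-outs. The count was 1 without 0.3 µM replicate 2, 4 without 0 µM replicate 1 and 2 without 0 µM replicate 2. Oligodendrocyte lineage markers had a median of −1.19 at 0.3 µM, with 4 of 18 lower (14 adjusted over the list alone; adjusted p = 1e-38, and 4.9e-06 with an estimated correlation). Pdgfra had values of −0.03 and −0.30 at 0.1 and 0.3 µM (adjusted p = 1 each). Kank4 was the gene higher at 0.3 µM and the single call at 0.1 µM, with ratios of 15.6 (4.31 to 128) and 18 (4.97 to 148) over the same 2 counts. The call at 0.1 µM was lost without 0.1 µM replicate 3 or either 0 µM replicate, that at 0.3 µM without 0.3 µM replicate 2 or 3 or either 0 µM replicate, and DESeq2 and limma called 0 genes at 0.1 µM.

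At 1 µM 5-fluorouracil the count was 406 without 1 µM replicate 2, 346 without 1 µM replicate 3, 389 without 0 µM replicate 2, 274 without a project term and 2477 against all 0 µM libraries. Within GRC327 the test called 1, 6 and 618 genes at 0.1, 0.3 and 1 µM and 778 along the trend, and Top2a had −0.95 there (adjusted p = 0.06). At 0.3 µM it called 0 genes without a project term and 43 against all 0 µM libraries. The trend called 791 genes (159 higher), with 494, 444 and 473 in the same leave-outs and 323 without a project term.

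Both compounds are pyrimidine antimetabolites, cytosine arabinoside a nucleoside with an arabinose sugar and 5-fluorouracil a free fluorinated base, and their effects were compared at matched concentrations by testing the difference itself. At 1 µM the 5-fluorouracil effect minus the cytosine arabinoside effect differed from 0 for 1984 genes, 1325 with a positive and 659 with a negative difference. For Fos the difference was −5.18 ± 0.66 (95% interval −6.51 to −3.84, adjusted p = 3.5e-08), and for Acan −4.86 ± 0.36 (−5.58 to −4.14). For Crh it was −5.38 ± 0.88 (−7.14 to −3.61, adjusted p = 6.7e-06), and −3.98 (0.11) without 5-fluorouracil 0 µM replicate 2. Nox1, an oxidase gene overlapping Cstf2 (−4.96 ± 0.61, −6.18 to −3.73), and Rgs13, a regulator of G-protein signalling (−4.57 ± 0.68, −5.93 to −3.20), completed the 5 largest negative differences. Rgs13 did not pass without a project term (0.097). The positive differences were led by the mitotic kinase gene Pbk (7.47 ± 0.75, 5.95 to 8.98), Kank4 (7.33 ± 0.93, 5.45 to 9.21), the cohesion protector Sgo2, which overlaps Kctd18 (7.27 ± 0.90, 5.46 to 9.08), Olfml1 (7.04 ± 0.49, 6.06 to 8.03) and Vstm4 (6.60 ± 1.36, 3.87 to 9.34, limma adjusted p 0.079). Pbk, Sgo2 and Vstm4 had 2, 1 and 0 counts with 1 µM cytosine arabinoside, and Kank4 had 2 at 0 µM of 5-fluorouracil, so these fitted differences depend on the prior count.

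Tested as lists, the differences at 1 µM were positive in 20 of 22 astrocyte markers, with a median of 3.35 (adjusted p = 1.7e-32), and in 24 of 38 cell cycle genes, with a median of 1.92 (3e-19). They were negative in 26 of 33 activity-regulated genes, with a median of −2.3 (1.6e-36), and in 10 of 19 GABAergic markers, with 1 positive and a median of −0.85 (6e-08). These list tests of the difference were added after the data were seen, and all 4 calls held with an estimated correlation (0.00060, 0.025, 0.00062 and 0.00096). Oligodendrocyte markers differed in 5 of 18, all positive, with a median of 0.59 (0.01, and adjusted p = 0.62 with an estimated correlation). At 0.1 and 0.3 µM the difference was called for 589 and 904 genes. Within GRC327 the counts were 529, 776 and 1377 at 0.1, 0.3 and 1 µM, without a project term 175, 403 and 925, and at 0.1 µM 250 without 5-fluorouracil 0.1 µM replicate 3 and 328 without 5-fluorouracil 0 µM replicate 2. Across the 15343 tested genes, whose effects are not independent replicates, the 2 effects at 1 µM had Pearson's r of 0.43 and Spearman's rho of 0.41. The 95% interval of the difference lay within ±1 for 7132 of 13584 genes at 1 CPM or more (52.5%), with a median half-width of 0.58. Of the genes called lower, 459 were shared against 99.5 expected, and of those called higher, 60 against 17.58 (Fisher's exact test, adjusted p = 7.3e-271 and 1.4e-20).

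**Figure D2:**
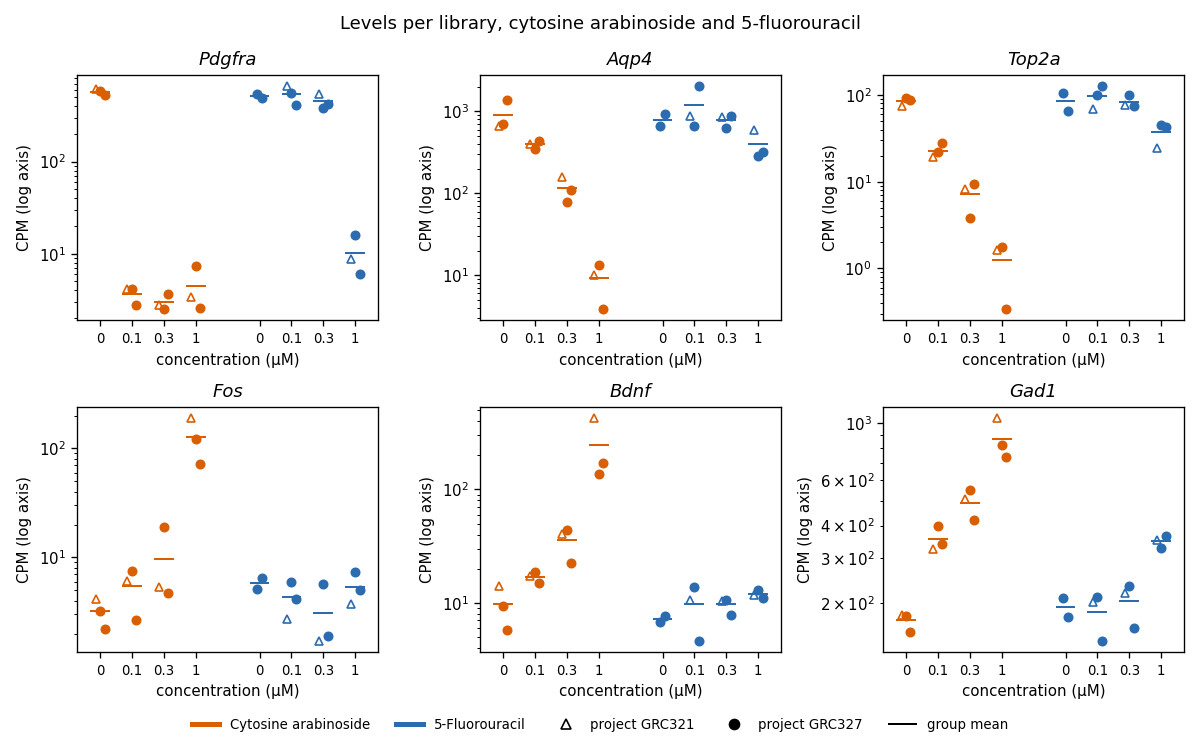
CPM per library on a log axis for Pdgfra, Aqp4, Top2a, Fos, Bdnf and Gad1 at 0, 0.1, 0.3 and 1 µM of cytosine arabinoside (orange) and 5-fluorouracil (blue), with lines at the group means and open triangles for project GRC321. Pdgfra averaged 4.44 CPM at 1 µM cytosine arabinoside and 10.3 CPM at 1 µM 5-fluorouracil, while Fos averaged 128 and 5.39 CPM.

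Haloperidol is an antipsychotic that blocks the dopamine D2 receptor, and its comparison asks what long exposure changed in the cultures. At 3 µM the interneuron peptide somatostatin, Sst (chromosome 11, 80358211 to 80359445), fell from 94.1 ± 24.9 to 36.4 ± 1.69 CPM (SD, n = 3 each), a log2 fold change of −1.33 ± 0.20 (SE; adjusted p = 0.00029). The 3 other genes called at 3 µM were also lower. Rgs8, a regulator of G-protein signalling (chromosome 13, 71086745 to 71141076), changed by −0.64 ± 0.12 (adjusted p = 0.027), Lynx1, a modulator of nicotinic receptors (chromosome 7, 115982876 to 115988091), by −0.58 ± 0.12 (0.046), and Nrip3 (chromosome 1, 174385424 to 174411142) by −0.43 ± 0.09 (0.046). GABAergic neuron markers had a median of −0.50 over 19 members, with 1 lower over all genes and 6 lower adjusted over the list alone (camera adjusted p = 3.9e-16, and 1.8e-05 with an estimated correlation). Vip stood at −1.07 ± 0.23 (adjusted p = 0.067), Slc32a1 at −0.72 ± 0.16 (0.11) and Gad2 at −0.62 ± 0.14 (0.11). These 3 passed with DESeq2 (0.014, 0.035 and 0.037) and, in an alternative chosen after seeing the data, with the outlying domoic acid library left out of the whole fit (0.047, 0.028 and 0.035). Gad2 also passed against all 0 µM libraries (0.00072). At 1 and 0.3 µM the list's medians were −0.27 (1.2e-08, and 0.0022 with an estimated correlation) and −0.19 (0.00061, and adjusted p = 0.088 with an estimated correlation), and Sst had −0.63 and −0.19.

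Other lists shifted with 3 µM haloperidol, with no member called over all genes. Activity-regulated genes had a median of −0.36 (adjusted p = 8.7e-07, and adjusted p = 0.26 with an estimated correlation), with 3 lower adjusted over the list alone. Astrocyte markers had a median of 0.24 (1.7e-06, and adjusted p = 0.19 with an estimated correlation) and oligodendrocyte markers of 0.25 (1.2e-06, and adjusted p = 0.079 with an estimated correlation), with 2 oligodendrocyte markers higher adjusted over the list alone. Pan-neuronal markers had a median of −0.14 (0.004, and adjusted p = 0.079 with an estimated correlation), with 2 of 18 lower adjusted over the list alone. Among them the neurofilament gene Nefl stood at −0.42 ± 0.11 (0.35), and passed with replicate blocks (0.038) and without 3 µM replicate 3 (0.022). Inflammation and reactive glia genes had a median of 0.32 (0.0045, and adjusted p = 0.26 with an estimated correlation), vascular and fibroblast markers of 0.63 (0.035, and adjusted p = 0.37 with an estimated correlation) and extracellular matrix genes of 0.20 (0.0026, and adjusted p = 0.12 with an estimated correlation). The unfolded protein list had −0.11 (0.0033, and adjusted p = 0.23 with an estimated correlation). Dopamine and monoamine signalling genes had a median of −0.15 (adjusted p = 0.16). The opioid peptide gene Penk stood at −0.75 ± 0.20 (adjusted p = 0.34) and the dopamine receptor gene Drd1 at −0.61 ± 0.18 (0.41). The count of 4 genes at 3 µM had 11 by DESeq2 and 4 by limma, and 788 genes had an unadjusted p under 0.05. It was 0 without 3 µM replicate 1, 1 without 3 µM replicate 2 or without 0 µM replicate 1 or 2, 0 within GRC327, where Sst had −1.14 (adjusted p = 0.81), 0 without a project term, and 14 with replicate blocks, where Vip (−1.06, 0.023) and Slc32a1 (−0.71, 0.011) passed. Gad2 passed without 0 µM replicate 3 (−0.76, 0.033). Sst lost its call without 3 µM replicate 1 (−1.17, 0.091), Rgs8, Lynx1 and Nrip3 in each of the 4 leave-outs just named, and Nrip3 also without 3 µM replicate 3 (0.086). The trend over the 4 concentrations called 7 genes, all lower (14 with replicate blocks, 0 within GRC327, 1 without 0 µM replicate 1 or 3 µM replicate 1, 2 without 3 µM replicate 2, 3 without 0 µM replicate 2). At 0.3 and 1 µM edgeR, DESeq2 and limma called 0 genes, with 317 and 531 at an unadjusted p under 0.05.

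**Figure D3:**
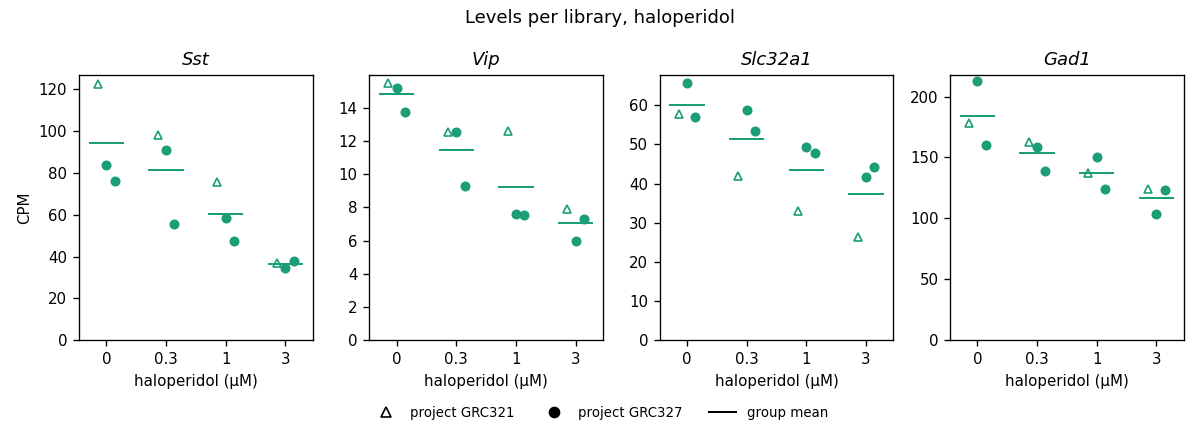
CPM per library of Sst, Vip, Slc32a1 and Gad1 at 0, 0.3, 1 and 3 µM haloperidol, with lines at the group means and open triangles for project GRC321. Sst lay between 34.58 and 37.85 CPM at 3 µM and between 76.09 and 122.5 CPM at 0 µM.

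Deltamethrin and cypermethrin are alpha-cyano pyrethroids, insecticides that act on voltage-gated sodium channels, and they differ in carrying bromine or chlorine on the vinyl group. Each was compared with its own 0 µM libraries, and then their effects with each other. With 10 µM deltamethrin the unfolded protein and integrated stress response list had a median of −0.26 over 26 members, none called (camera adjusted p = 9e-07, and 0.036 with an estimated correlation). Within GRC327 the 4 members with the smallest p were closer to 0, with Atf4, a stress transcription factor, at −0.13 against −0.41 in all libraries, the asparagine synthetase gene Asns at −0.11 against −0.29, the amino acid transporter gene Slc7a3 at −0.26 against −0.50 and the transcription factor gene Xbp1 at −0.25 against −0.34. The GRC321 library at 10 µM had 6.63% of its counts in mitochondrial genes, against 4.21% to 4.91% in the other GRC321 libraries of deltamethrin. The p53 targets had a median of −0.13 (adjusted p = 0.021, and adjusted p = 0.13 with an estimated correlation). Potassium channel genes had 0.14 (0.003, and adjusted p = 0.26 with an estimated correlation) and activity-regulated genes of 0.13 (0.0086, and adjusted p = 0.64 with an estimated correlation). The 6 genes with the smallest p all failed the correction. Cartpt, a neuropeptide gene, had −1.62 ± 0.39 (adjusted p = 0.91), and Calb2, the calretinin gene, −0.87 ± 0.24, the translation repressor gene Eif4ebp1 −0.99 ± 0.28, Tmtc4 −0.65 ± 0.18, Rgs8 0.43 ± 0.12 and Gad1 0.56 ± 0.16 (0.96 each). With edgeR 0 genes were called at 1, 3 and 10 µM and along the trend, with 793, 293, 760 and 620 at an unadjusted p under 0.05. DESeq2 called 0, 0, 1 and 2, and limma 0, 0, 1 and 1. The lone 0.3 µM library, assumed to vary like the other groups, gave 0 calls by edgeR, with 350 genes at an unadjusted p under 0.05. Within GRC327 all counts were 0, and Calb2, Eif4ebp1 and Gad1 had −0.23, −0.60 and 0.37.

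With 10 µM cypermethrin the voltage-gated sodium and calcium channel genes had a median of 0.18 over 24 members, none called (camera adjusted p = 0.00028, and adjusted p = 0.26 with an estimated correlation). Within GRC327 the 4 members with the smallest p, all calcium channel subunit genes, were closer to 0, with Cacna1a at −0.03 against 0.41 in all libraries, Cacna1g at 0.09 against 0.39, Cacna1h at 0.16 against 0.44 and Cacnb1 at 0.15 against 0.36. Cacna1a and Cacna1h passed without 0 µM replicate 2 (0.84, adjusted p = 0.02, and 0.71, 0.025). Presynaptic vesicle genes had a median of 0.16 (0.0026, and adjusted p = 0.27 with an estimated correlation). Activity-regulated genes had a median of 0.25 (0.021, and adjusted p = 0.64 with an estimated correlation), a call that ended with replicate blocks (0.24), and the unfolded protein list had −0.15, with 0.076 that became 0.046 with blocks. The 6 genes with the smallest p had an adjusted p of 0.44 each. Tmco3 stood at 0.90 ± 0.21, the glycosylation enzyme gene Rxylt1 at −0.62 ± 0.14, Ndufaf7, a complex I assembly factor, at −0.78 ± 0.19, Phyhip at 1.54 ± 0.39, the calmodulin kinase kinase gene Camkk1 at 0.52 ± 0.13, and Chn2 at −0.61 ± 0.16. With edgeR 0 genes were called at 1, 3 and 10 µM and along the trend, with 774, 933, 1105 and 1182 at an unadjusted p under 0.05. DESeq2 called 3, 2, 2 and 1, limma 0, 1, 0 and 0, and GRC327 alone 0 throughout, where Tmco3, Rxylt1 and Ndufaf7 had 0.61, −0.41 and −0.21. The single 0 µM library of GRC327 belonged to the second run of sample numbers, so the first run had no 0 µM library of its own. Without 0 µM replicate 2, which left 1 library at 0 µM, the counts were 84, 316, 386 and 418, and of the 6 genes Tmco3 (1.36, adjusted p = 0.012), Rxylt1 (−0.82, 0.016), Ndufaf7 (−1.25, 0.0041) and Chn2 (−0.76, 0.038) passed.

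The deltamethrin effect minus the cypermethrin effect differed from 0 for 0 genes at 1, 3 and 10 µM by edgeR and limma, with 1154, 590 and 1115 at an unadjusted p under 0.05 and 2, 4 and 2 by DESeq2. The smallest p values at 10 µM belonged to Tmco3 (difference −1.18, 95% interval −1.73 to −0.63) and Rxylt1 (0.80, 0.41 to 1.19), at an adjusted p of 0.5. The 95% interval lay within ±1 for 8555 of 13584 genes (63%) at 10 µM, with a median half-width of 0.57, so differences up to that size stay open for many genes. In list tests added after the data were seen, no list of the difference at 10 µM passed, and the lowest adjusted p was 0.061, for the sodium and calcium channel genes. At 3 µM the unfolded protein and integrated stress response list of the difference had a median of −0.26 and passed (adjusted p = 0.004, and adjusted p = 0.23 with an estimated correlation), while at 1 and 10 µM it had 0.057 and 0.23. Across genes, which are not independent replicates, the 2 effects at 10 µM had Pearson's r of −0.07 and Spearman's rho of −0.05. Without cypermethrin 0 µM replicate 2 the counts at 1, 3 and 10 µM were 10, 12 and 296, with Tmco3 at −1.65 (0.0085) and Rxylt1 at 1.0 (0.015), and GRC327 alone gave 0.

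Domoic acid is a kainate-type glutamate receptor agonist, and its comparison asks what exposure at up to 1 µM changed. At 1 µM the oligodendrocyte lineage markers had a median of −0.28 over 18 members, none called (camera adjusted p = 0.0022, and adjusted p = 0.28 with an estimated correlation). Ionotropic glutamate receptor genes had a median of −0.11 (0.0019, and adjusted p = 0.16 with an estimated correlation), with 2 lower adjusted over the list alone. GABA receptor genes had −0.10 (0.017, and adjusted p = 0.26 with an estimated correlation) and cell cycle genes −0.07 (0.012, and adjusted p = 0.64 with an estimated correlation). The 6 genes with the smallest p all failed the correction. Stac2 stood at 1.30 ± 0.29 (adjusted p = 0.74), Map4k1 at 1.97 ± 0.48 (0.93), the growth factor binding gene Igfbp5 at 0.61 ± 0.15 (0.93) and Mustn1 at 1.16 ± 0.31 (0.97). Cacng2 and Cacna2d3 had −0.52 ± 0.13 and −0.61 ± 0.16. Against all 0 µM libraries Igfbp5 (0.68, adjusted p = 0.0028), Cacna2d3 (−0.72, 0.0045) and Stac2 (1.02, 0.048) passed. In GRC327 the pooled 0 µM libraries lay on both sides of the fourth principal component, but all domoic acid libraries on the positive side. These passes may therefore hold part of that difference between samples. At 0.1 and 1 µM and along the trend edgeR called 0 genes, with 341, 553 and 880 at an unadjusted p under 0.05, and DESeq2 called 1, 0 and 1 and limma 0. At 0.3 µM 231 genes were called, 185 higher and 46 lower, but this count rested on single libraries. It was 0 without 0.3 µM replicate 2, the library farthest from the rest on the third principal component, 0 without 0 µM replicate 2 or 3, 534 without 0 µM replicate 1, 2942 without 0.3 µM replicate 1 and 1538 without 0.3 µM replicate 3. DESeq2 called 619 and limma 94, and without a project term the count was 0. Within GRC327 it was 2109 (0 at 0.1 and 1 µM and along the trend), and 879 of these genes (41.7%, exact 95% interval over genes 39.6 to 43.8) had the same sign in the single GRC321 pair, against 47% of the genes not called.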

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

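In this part the tests against the pan-neuronal markers and against the 5-fluorouracil values were chosen after the result was seen. The tests within each project and of the scaling were chosen before.

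The results given here were singled out because the effects of 2 related compounds differed, in a test of the difference itself, 5-fluorouracil minus cytosine arabinoside at matched concentrations. The number of genes with a difference was 589 at 0.1 µM, 904 at 0.3 µM and 1984 at 1 µM. Among single genes at 1 µM, Pbk (7.47), Sgo2 (7.27), Olfml1 (7.04) and Vstm4 (6.6) had positive log2 differences because their counts fell from 407 to 2, 390 to 1, 1185 to 5 and 39 to 0 with cytosine arabinoside. With 5-fluorouracil they went from 227 to 278, 248 to 182, 803 to 492 and 33 to 31, over 2 and 3 libraries. Kank4 (7.33) had 50 and 6 counts with cytosine arabinoside and 2 and 47 with 5-fluorouracil. The negative differences of Crh (−5.38), Fos (−5.18), Nox1 (−4.96), Acan (−4.86) and Rgs13 (−4.57) went with rises under cytosine arabinoside, for example from 126 to 4577 counts of Fos and from 593 to 13004 of Acan. With 5-fluorouracil those genes had 179 and 162, and 572 and 442 counts.

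The rise of the activity-regulated genes with 1 µM cytosine arabinoside, by a median of 2.80 (SD 1.52 over members), was weighed against 4 explanations. A larger neuronal share of the RNA would raise pan-neuronal markers alike, but their median was 0.13 (SD 0.7), and a project difference is argued against by medians of 2.65 within GRC327 and 3.27 in the GRC321 pair. With DESeq2 size factors the median was 2.82, which argues against the choice between TMM and DESeq2 scaling as the source. Both scalings assume that most genes keep their level, so the median of all genes (0.045) was bound to stay small. A shift common to most genes therefore cannot be tested this way. The fall of oligodendrocyte markers alone is argued against by 5-fluorouracil, where those markers fell by a median of 3.61 and the activity list had 0.13 (SD 0.5). A candidate explanation is a change in neuronal activity after the astrocyte transcripts fell, and since network firing was not analysed here and astrocyte loss was not separated from the compound, both stay untested.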

How the results depend on the processing

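The alternatives were chosen before the data were examined, except leaving domoic acid 0.3 µM replicate 2 out of the whole fit and thinning it, which were chosen after seeing the data. No value changed sign with a call under any alternative. With 1 µM cytosine arabinoside 88 of the 91 called named genes kept their call in all settings and 90 in all leave-outs, and with 1 µM 5-fluorouracil 23 and 20 of 45. For the 5-fluorouracil minus cytosine arabinoside difference 8 and 9 of 10 did, for 5-fluorouracil 0.3 µM 0 and 1 of 7, and for haloperidol 3 µM 0 and 0 of 4. Of 47 list calls in 162 tests, 12 held with an estimated correlation and 27 with fry, which asks whether a list moves one way without comparing it with other genes. Pooled 0 µM libraries have no value for the differences between compounds or the trends. Small changes were often missed at this depth and number of libraries in simulated data, where 9% to 32.3% of genes with a log2 change of 0.5 were called.

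Numbers of genes called are given for every setting that moved them by over 1.5 times, and the cause was not tested unless stated. The DESeq2 test gave 0 for 5-fluorouracil 0.1 µM, 3, 2 and 2 for cypermethrin 1, 3 and 10 µM and 1 for its trend, 1 for deltamethrin 10 µM and 2 for its trend, 1 and 619 for domoic acid 0.1 and 0.3 µM and 1 for its trend, 11 for haloperidol 3 µM and 17 for its trend. For the pyrethroid difference it gave 2, 4 and 2 at 1, 3 and 10 µM, and 122 genes shared as higher between the antimetabolites. DESeq2 size factors gave 2 for haloperidol 3 µM. limma on the deposited CPM gave 0 for 5-fluorouracil 0.1 µM, 1 for cypermethrin 3 µM, 1 for deltamethrin 10 µM and its trend, and 94 for domoic acid 0.3 µM. A minimum count of 50 gave 0 for 5-fluorouracil 0.1 µM, since Kank4 was then not tested, and 422 for domoic acid 0.3 µM. No filter gave 152 for domoic acid 0.3 µM and 2 for haloperidol 3 µM. GRC327 alone, with fewer samples, gave 896 for cytosine arabinoside 0.1 µM, 2109 for domoic acid 0.3 µM and 0 for haloperidol 3 µM and its trend.

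Without a project term the spread between projects entered the error. The counts were 505, 1381 and 3113 for cytosine arabinoside and 3199 for its trend, 0 and 274 for 5-fluorouracil 0.3 and 1 µM and 323 for its trend, 0 for domoic acid 0.3 µM and for haloperidol 3 µM and its trend, and 175, 403 and 925 for the antimetabolite difference. A single project term gave 2 for haloperidol 3 µM. A fit per compound gave 249 and 600 for the antimetabolite difference at 0.1 and 0.3 µM, 0 and 2 for 5-fluorouracil 0.1 and 0.3 µM, 1 for cypermethrin 10 µM, 486 and 1591 for cytosine arabinoside 0.1 and 0.3 µM, 2 for deltamethrin 1 µM, 2 for the pyrethroid difference at 3 µM, 0 for domoic acid 0.3 µM and 11 for the haloperidol trend. Pooled 0 µM libraries gave 0, 43 and 2477 for 5-fluorouracil, 2285 for cytosine arabinoside 0.1 µM, 3 for deltamethrin 10 µM, 3, 1270 and 5 for domoic acid, and 14 for haloperidol 3 µM. Replicate blocks gave 14 for haloperidol 3 µM and for its trend and 91 genes shared as higher. For 5-fluorouracil 0.3 µM and domoic acid 0.3 µM, whose numbers did not pass the check for pairing, they gave 16 and 481. For 5-fluorouracil that check was missed narrowly, its 1 µM count was 753 with blocks, and the fourth principal component set its GRC327 runs apart (8.6 to 15.2 against −15.4 to −13.6), so its runs may pair the libraries. The split was not particular to 5-fluorouracil. The GRC327 libraries of domoic acid all lay on the positive side (2.2 to 18.3) and those of deltamethrin on the negative side (−18 to −8). For these 2 compounds the spread within GRC327 therefore leaves out the difference between the sides. Their comparisons with the pooled 0 µM libraries, which lie on both sides in GRC327, take that difference in. Among the compounds that did not pass, blocks also brought calls for cholesterol biosynthesis with 10 µM deltamethrin (0.032) and, with 1 µM 5-fluorouracil, for choroid plexus and ependymal markers (0.022), potassium channels (0.049), Vip, Mvd and Ppp1r1b. Apart from Nefl with 3 µM haloperidol (adjusted p = 0.038) and the genes and lists given with their results, blocks changed no other call of a named gene or list for haloperidol, cypermethrin and cytosine arabinoside. Leaving out domoic acid 0.3 µM replicate 2 gave 0 for domoic acid 0.3 µM, 13 for 5-fluorouracil 0.3 µM, 8 for haloperidol 3 µM and 11 for its trend, and thinning gave 74.

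Leaving out 1 library at a time gave, from lowest to highest, 0 to 6 for haloperidol 3 µM and 1 to 10 for its trend, 0 to 2942 for domoic acid 0.3 µM, 0 to 84, 0 to 316 and 0 to 386 for cypermethrin 1, 3 and 10 µM and 0 to 418 for its trend. Cytosine arabinoside had 906 to 1184, 2144 to 2455 and 4467 to 5599, and 4656 to 5642 for its trend. 5-Fluorouracil had 0 to 1, 1 to 9 and 346 to 654, and 444 to 843 for its trend. The pyrethroid difference had 0 to 10, 0 to 12 and 0 to 296 at 1, 3 and 10 µM, and the antimetabolite difference 250 to 686, 643 to 901 and 1430 to 2197. Every leave-out of the remaining comparisons gave 0. The highest values for cypermethrin and the pyrethroid difference came without cypermethrin 0 µM replicate 2.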

Other observations

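Of the tests in this part, all splits and regroupings of the libraries and those of domoic acid 0.3 µM were chosen after the result was seen, the thinning test with the number of calls after thinning already known. The pair of tests on cypermethrin was chosen before their results were seen.

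With 1 µM cytosine arabinoside, members of further gene groups changed, although no list call among these groups held with an estimated correlation. Interferon response genes fell in 8 of 18 members (11 adjusted over the list alone), with a median log2 fold change of −1.48, or −1.03 with genes near 0 counts at their bound (camera adjusted p = 0.004, and adjusted p = 0.085 with an estimated correlation). Vascular and fibroblast markers fell in 7 of 13 (adjusted p = 0.22, and 0.049 with replicate blocks), including Pdgfrb, the receptor of pericytes, at −4.18 ± 0.40. Potassium channel genes rose in 13 of 22 and fell in 4 (adjusted p = 0.0019, and adjusted p = 0.26 with an estimated correlation). The channel that fell most by p, Kcnj10 (−5.09 ± 0.28), is the astrocytic one, while Kcna1 rose by 1.85 ± 0.21. Presynaptic vesicle genes rose in 13 of 23 and fell in 2 (adjusted p = 0.0026, and adjusted p = 0.28 with an estimated correlation), with Cplx1 at 0.97 ± 0.10. Stress genes of the unfolded protein and integrated stress response went both ways, 15 higher and 6 lower of 26 (adjusted p = 0.16), with the serine synthesis enzyme Phgdh at −3.80 ± 0.18 and the cystine transporter Slc7a11 at −4.83 ± 0.32.

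Other lists did not pass with 1 µM cytosine arabinoside although members did. Of 28 p53 targets 6 rose and 7 fell (adjusted p = 0.96), the kinase gene Plk3 at 1.84 and the death receptor gene Fas at −2.56. Nucleotide metabolism genes had 2 higher and 7 lower of 22 (adjusted p = 0.67), with the thymidine kinase gene Tk1 at −2.11 ± 0.27. Glutamatergic neuron markers had 3 higher and 6 lower of 16 (0.77), with the vesicular transporter Slc17a6 at 1.0 and Camk2a at −0.79, a call that ended without a project term. Ionotropic glutamate receptors had 5 higher and 7 lower of 25 (0.77; median 0.01, mean −0.23), GABA receptors 7 and 2 of 14 (0.09), and sodium and calcium channels 6 and 8 of 24 (0.97). Lysosome genes had 1 higher and 10 lower of 26 (0.12), apoptosis and necrosis genes 4 and 4 of 16 (0.97), xenobiotic response genes 2 and 1 of 6 (0.8), and choroid plexus and ependymal markers 0 and 1 of 8 (0.73). Microglia and erythroid markers had fewer than 5 tested members.

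Further lists passed with 1 µM 5-fluorouracil, though none of those below did with an estimated correlation. NRF2 targets had a median of −0.24 and 4 of 19 lower (adjusted p = 0.0014, and adjusted p = 0.28 with an estimated correlation). Extracellular matrix and growth factor genes had −0.34 and 5 of 25 lower (0.012, and adjusted p = 0.23 with an estimated correlation). Lysosome genes had −0.16 and 1 of 26 lower (0.031, and adjusted p = 0.39 with an estimated correlation), and fatty acid synthesis genes −0.23 and 1 of 16 lower (0.043, and adjusted p = 0.59 with an estimated correlation). Dopamine and monoamine signalling genes had 0.26 and 1 of 19 higher (0.02, and adjusted p = 0.13 with an estimated correlation), and sodium and calcium channel genes 0.12 and 1 of 24 higher (0.012, and adjusted p = 0.57 with an estimated correlation). Cholesterol biosynthesis genes had 0.18 and none called (0.0057, and adjusted p = 0.64 with an estimated correlation).

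The first principal component (29.2% of variance) separated GRC321 from GRC327, and the median percent of counts in mitochondrial genes was 4.745 and 2.82 in the 2 projects. The second component (17.7%) ordered the cytosine arabinoside libraries, from −40.8 to −23.8 at 0.1 µM, −72.7 to −48.4 at 0.3 µM and −108.5 to −99.9 at 1 µM, with 5-fluorouracil 1 µM from −35.6 to −19.3.

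The 231 calls at 0.3 µM domoic acid were weighed as the work of 1 library or of the compound. Without replicate 2 there were 0 calls, while the count rose to 2942 without 0.3 µM replicate 1 and also rose without replicate 3. Within the 0.3 µM group the calls therefore rested on replicate 2. Leaving out either GRC327 library of 0 µM alone also gave 0, so a count of 0 is not particular to replicate 2. Replicate 2 also lay at −76.2 on the third principal component, against −31.4 to 34.4 in the other libraries. Its higher total count stays open: thinning from 22.6 M to 9 M left 97.7% of the median size of the fold changes (0.93 to 0.91, SD 0.53), but random thinning keeps the expected fold changes whatever the cause, so the value set in advance could not decide, and the calls fell to 74. A bias by gene span, perhaps from RNA quality, stays open: the median deviation in replicate 2 differed by 0.57 between genes spanning at most 4.8 kb and at least 66.7 kb, against −0.2 to 0.3 in the other libraries, and 64 ribosomal protein genes deviated by 1.29 ± 0.83 (SD), against −0.56 to 0.79. An effect of 0.3 µM domoic acid stays open too, since the 41.7% of the GRC327 calls with the same sign in GRC321, against 47% of the genes not called, rest on a single pair of libraries.

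Cypermethrin at 10 µM had 386 calls without 0 µM replicate 2 (195 higher, 191 lower), when the single 0 µM library left was replicate 1. That library lay farther from the other GRC321 0 µM libraries than any of them from the rest, at a root mean square log2 distance of 0.69 against 0.51 to 0.6 among 5 libraries, which makes it a candidate source of these calls. Whether an effect of cypermethrin is hidden by replicate 2 cannot be told apart from this. Among the genes called without replicate 2, 66.8% (exact 95% interval over genes 61.9 to 71.5) had the same sign against the 10 GRC327 0 µM libraries of the other compounds. This share lay between the levels set beforehand for either reading. The 10 µM libraries in this check also entered the fit that chose the genes, which favours the same sign. The genes are not independent replicates either.

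The calls were also counted for other splits of the same libraries. The gene filter, TMM factors and negative binomial spread were held at those of the main fit, made with the real groups. The coefficients and the quasi-likelihood spread were refitted, so the splits do not repeat the whole procedure. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Cytosine arabinoside had 1401, 2703 and 5520 calls at 0.1, 0.3 and 1 µM and at most 182, 92 and 721 in the others, so 1 split of 10, the real one, reached each count. For haloperidol 3 µM the real split gave 4 and the highest other 1, and again 1 split of 10 reached it. For domoic acid 0.3 µM, 3 of 10 splits gave as many as the real 231, with a highest of 1101, several times the real count, which points to a structure of the samples. For haloperidol 0.3 and 1 µM, domoic acid 0.1 and 1 µM and deltamethrin 1, 3 and 10 µM the real count was 0, which all 10 splits reach, and the highest other was 1 for haloperidol 0.3 µM and 0 for the rest. Where the sample numbers pair the libraries, the 3 other splits that part as many pairs as the real one gave at most 0 for haloperidol 3 µM and 0, 0 and 155 for the cytosine arabinoside concentrations, and the 6 that part fewer gave the higher values. For the trends, 21 regroupings each were counted within the projects, without keeping the runs of sample numbers. For haloperidol (7 against a highest of 0) and cytosine arabinoside (5547 against 2790) 1 of 21, the real one, reached the count, a share under 0.05 and the smallest that 21 can give. For haloperidol, whose trend had 0 calls within GRC327, chance is therefore not taken as excluded. It cannot be excluded for domoic acid and deltamethrin, where the real count was 0 and all 21 reached it, with highest values of 860 and 0.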
